A study of Mus musculus with 2 samples.

How the data were processed

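H3K27me3 ChIP-seq was carried out on activated regulatory T cells from 1 biological replicate of an adult male mouse, 4 months old, and 2 technical replicates were deposited. Samples were placed in 1 group by the cell type in the labels, and the technical replicate numbers were taken from the labels. Since both libraries come from 1 biological replicate, no mean ± SD over animals is given and n is 1.

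The authors deposited 1 table of whole-number counts per library, with a region number from 1 to 33643 and a value. Per the labels and the deposited text notes, each table was made from the library's own alignments on mm10 together with a separate reference file, and its kind is called enrichment. The aligner, the read filters, the counting program, any removal of duplicate reads, any background subtraction and the definition of the regions are not given in the sources used here. The deposited counts were taken as unscaled for these reasons: they are whole numbers, the totals differ between the libraries, and the spread between the libraries, over all regions, equals binomial sampling of the counts. The name enrichment would fit a ratio to a control, but no control library is used here. Whether the counts were corrected for region length, mappability or copy number is not stated and could not be checked. Without such a correction, a long, repeated or highly accessible region can have a high count without a higher density of the mark. Whether a count is a read or a fragment is not stated. Whether duplicate reads were kept is not stated either, and duplicates would make counting intervals too narrow.

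Depth was 315305 counts for replicate 1 and 339420 for replicate 2 over the regions. A limit of 3 counts corresponds to 9.51 and 8.84 in every 1000000 counts. The median count per region was 6 and 7, so that single regions have wide counting errors, and a pooled count of 55 has an exact Poisson 95% interval of 41.4 to 71.6. Replicate 1 had 480 regions at 0 and replicate 2 had 402.

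The comparisons, gene lists, the rule for named features and most alternatives were fixed before the data were examined. The rule named the 10 regions with the highest mean over both libraries that were also in the top 5% of each library. It also named the highest and lowest members of each gene list, and 21 genes in every case. The 5 regions with the largest difference between the libraries were named as well. As the files pair no region number with a coordinate or a gene symbol, 23 gene lists (HOX clusters, developmental regulators, T cell and other lineage genes, and housekeeping genes among them) and the levels per chromosome were not evaluated. For the same reason at most 2 region numbers in each direction are printed. The mm10 reference was not used, and no region was assigned to a gene or chromosome from its place in the list.

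From the counts, Pearson and Spearman correlations across regions, a chi-square statistic of both libraries over regions, and the overlap of the top 5% of regions were computed. Log2 values used a pseudocount of 0.5. Each was set against 1000 binomial splits of the pooled counts at the ratio of the library totals, which hold counting noise only. Regions 2-fold or more apart were counted after scaling to the library totals. Single regions, and 8 levels of the pooled count, were tested by the exact two-sided binomial test with Benjamini-Hochberg adjustment at 0.05. No count model across groups was fitted, because there is 1 group. Runs of low counts were found as the stretches of consecutive numbers with the highest sum of scores, with 0.3 for a region at or below the median and -0.7 for any other, and the 3 highest-scoring of 6 runs were kept. Their levels were compared by the ratio of interquartile means with 2000 bootstrap draws over regions, with ratios of medians and of means, each library alone and edges from the other library as alternatives. They were also set against preceding counts halved by binomial thinning. The share of replicate 1 in the strongest regions was tested for every number of regions up to 1682 by the largest departure in 1000 binomial splits. These tests treat counts as independent. The order was tested with 100 shuffles of single regions and 100 shuffles of blocks of 20 neighbouring numbers, the latter without the 3 runs.

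The procedures were tested before use on data simulated from the deposited counts. With 200 changed regions among 33643, the binomial test called 50% of those changed by 4-fold, 5% of those changed by 2-fold, and 1 of 33443 unchanged regions. The changed regions had 10 or more pooled counts before the change, and each was raised in replicate 2, which added counts to it. A planted run at numbers 5001 to 5500, in the counts put in shuffled order, was found at 4999 to 5506. Shuffling removes the correlation of neighbouring numbers, so edges in the deposited order can be less exact. Alternatives were untransformed counts, pseudocounts of 0.1 and 1, a restriction to regions above the median, quantile normalization, median centring, the top 1% and 10%, thresholds of 1.5-fold and 4-fold, and each library alone. The test per region, the levels and the search along the numbers were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.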

Results

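The trimethyl mark on lysine 27 of histone H3 (H3K27me3) was measured by chromatin immunoprecipitation and sequencing in activated regulatory T cells of the mouse. H3K27me3 is laid down by a Polycomb repressive complex and is found mostly at silent genes. Regulatory T cells are the lineage of T cells that restrains immune responses and depends on the transcription factor Foxp3. The cells came from an adult male, 4 months old, of a line that carries an inducible Cre recombinase at Foxp3 and a Cre-dependent YFP reporter at Rosa26. There was 1 biological replicate, sequenced as 2 technical replicates, and no second cell state, antibody or input library is used here. The study therefore holds 1 comparison between samples, that of the technical replicates, and the spread between them is technical. Each library gave a count for the same 33643 numbered regions. Replicate 1 held 315305 counts in these regions and replicate 2 held 339420, so the pooled depth was 654725.

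H3K27me3 counts were unevenly spread over the regions. A small set of regions with high counts stood above a large set of regions with low counts. The median region had 13 pooled counts, with an exact Poisson 95% interval of 6.92 to 22.2, and the mean was 19.5. The variance of the pooled counts over regions was 33.4 times their mean, where counts drawn at 1 common level would give a value near 1. Of the 33643 regions, 5781 (17.2%) reached 2 times the median, and these held 48.4% of all counts (Wilson 95% interval 48.2% to 48.5%). Regions at 4 times the median numbered 1854, or 5.51% of regions, and held 27.9% of the counts. Regions at 8 times the median numbered 586 and held 14.1%, and the 77 regions at 16 times the median held 3.41%. The lower-ranked 16822 regions held 21.4% of the counts. Only 45 regions had a count of 0 in both libraries, which allows a level of up to 4.58 counts in every 1000000. Intervals and limits cover counting error only.

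The strongest region, number 6635, had 594 counts in replicate 1 and 548 in replicate 2. Its pooled count of 1142 (exact Poisson 95% interval 1077 to 1210) was 87.8 times the median region. Region 18076 followed with 477 and 437 counts, a pooled count of 914, which was 70.3 times the median. The remaining members of the 10 strongest regions had pooled counts from 374 to 617. All 10 lay in the top 5% of both libraries, as the rule for naming them required. The 10 nearest numbers around region 6635 had a median of 18 pooled counts and a highest count of 42. Those around region 18076 had a median of 20 and a highest count of 105. The files pair no region number with a position or a gene, so the genes under these regions are not named here. Counts were not divided by region length, which is not used here, so a long region and a densely marked region look alike.

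The same regions had high counts in both technical replicates. The top 5% of regions, at 27 or more counts, numbered 1723 in replicate 1. At 29 or more counts they numbered 1712 in replicate 2. The libraries shared 1452 of them, where independent lists of these sizes would share 87.7. Shared regions made up 84.3% of the set of replicate 1 and 84.8% of that of replicate 2. In 1000 random binomial splits of the pooled counts, which hold sampling noise alone, the shared number lay between 1431 and 1473 in the central 95%. The overlap thus differed from that of a perfect technical repeat by less than the sampling noise.

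**Figure D1:**
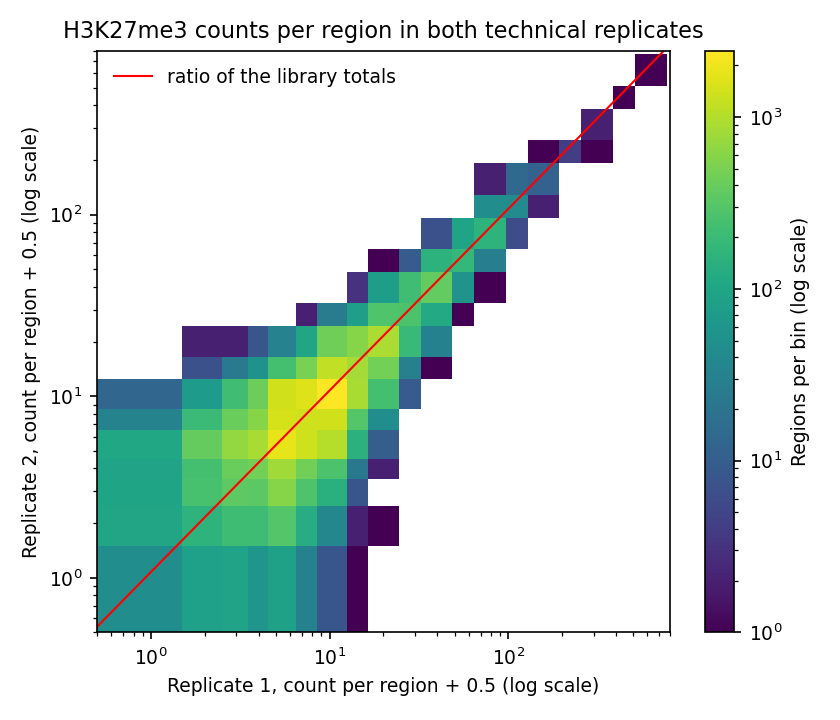
Counts per region in technical replicate 1 (x axis) and replicate 2 (y axis), both plus 0.5 on log scales, with the number of the 33643 regions per bin as colour; the red line is the ratio of the library totals. The cloud is wide at low counts and narrows along the line towards region 6635, at 594 and 548 counts.

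Across regions, counts of the libraries correlated at Pearson r = 0.941 and Spearman rho = 0.69. On the log2 scale, with 0.5 added to each count, r was 0.72. Regions are not independent replicates, and these values describe 2 libraries of 1 sample. Binomial splits gave central 95% ranges of 0.941 to 0.943 for the Pearson r of counts, 0.687 to 0.695 for rho and 0.715 to 0.724 for the r of log2 values. A chi-square test of both libraries over the 33598 regions with a count gave 33601 on 33597 degrees of freedom, a ratio of 1.00 (simulated one-sided p = 0.476 from 1000 splits). The ratio in the splits lay between 0.986 and 1.01 in the central 95%. In simulated libraries with an added coefficient of variation of 0.1 per region, it rose to 1.10. Over all regions the libraries differed by no more than the sampling noise, and they were counted as 1 sample.

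The precision of a single region followed its depth. The SD of the log2 ratio between the libraries was 1.5 in regions with 1 to 4 pooled counts, 0.80 in those with 10 to 19 and 0.23 in those with 100 or more. A total of 6885 regions differed by 2-fold or more between the libraries, and binomial splits gave 6633 to 7130. Region 19428 had 13 counts in replicate 1 and 0 in replicate 2, and region 23616 had 16 and 1. Region 14160 had 1 count in replicate 1 and 17 in replicate 2, and region 16685 had 1 and 16. None of these differences passed an exact binomial test with Benjamini-Hochberg adjustment (adjusted p = 1 for each). By this test 0 of 33598 regions differed at an adjusted p under 0.05, and 1029 had an unadjusted p under 0.05, where 20 binomial splits gave 1015 to 1164. In simulated counts for these 33643 regions, only regions with 10 or more pooled counts were changed, each upwards in replicate 2. The shares called therefore do not cover regions with fewer counts. Of 100 regions changed by 4-fold, 50 were called, and of 100 changed by 2-fold, 5 were called. Raising replicate 2 also added counts, so changed regions were deeper than in the deposited counts. These shares can thus be too high for the deposited depth. A 2-fold difference of a typical region was therefore not detectable at this depth.

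One set of regions departed from the common ratio of the libraries. The 15 regions with 300 or more pooled counts, a level set after the values were seen, took 51.5% of their counts from replicate 1 (exact binomial 95% interval 50.4% to 52.7%). Replicate 1 made up 48.2% of all counts. Relative to the library totals, these regions were 1.15-fold higher in replicate 1 (95% interval 1.09 to 1.20). The two-sided exact binomial test on their summed counts gave p = 4.0e-09 (adjusted p = 3.2e-08 over 8 levels). Of the 15 regions, 12 lay above replicate 1's share of all counts. Without the 2 strongest regions the share was 51.3%. The 8 regions before number 20113, with 345 to 1142 pooled counts, were at 52.7%. The 7 later ones, with 317 to 435 pooled counts, were at 49.3% and did not pass the test (1.05-fold, 95% interval 0.97 to 1.13, two-sided exact binomial p = 0.25). The other 7 levels did not pass the test, and their shares lay between 47.8% and 48.2%. The test compares the counts of these libraries, treats them as independent, and does not compare biological samples.

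**Figure D2:**
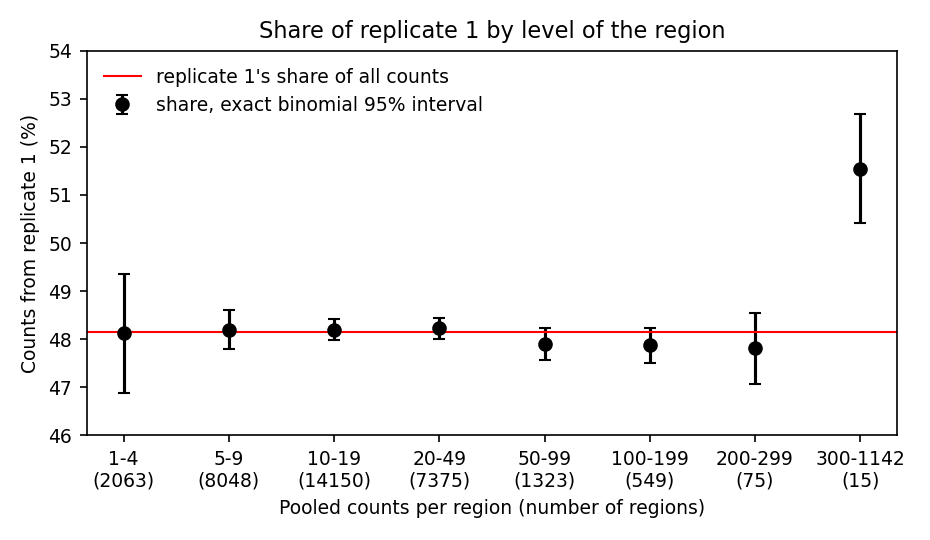
Share of the counts that came from replicate 1 (y axis, percent) at 8 levels of the pooled count (x axis, with the number of regions), with exact binomial 95% intervals; the red line is the share over all regions, 48.2%. The 15 regions with 300 or more counts sit at 51.5%, above the line, and the other levels lie between 47.8% and 48.2%.

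Counts also varied along the region numbers. In full blocks of 100 consecutive numbers outside the 3 runs described here, the median pooled count ranged from 10 to 20. Numbers 20113 to 20633 formed a run of 521 regions with a median of 6 pooled counts, against 13 in the numbers before it. The interquartile mean of the run, which is the mean of the central part of its counts, was 0.43 times that of the preceding numbers (95% bootstrap interval 0.40 to 0.46). The ratio was 0.42 in replicate 1 and 0.43 in replicate 2, and the ratio of medians was 0.46. A second run, of 105 regions from 25835 to 25939, had a median of 5 against 13 and a ratio of 0.38 (0.32 to 0.45). The third, of 55 regions from 33504 to 33558, had a median of 6 against 15 and a ratio of 0.40 (0.31 to 0.50). Its far edge was not sharp, as the 85 numbers that follow it, to the end of the list, had a median of 8. It also stood little apart from other stretches, with a score of 10.5 against 9.5 for the next-ranked run. Shuffles of blocks from outside the 3 runs reached up to 14.2. The edges were found from the counts themselves. With edges taken from replicate 1 alone, the ratios in replicate 2 were 0.43, 0.34 and 0.34 for the first, second and the third run. With edges from replicate 2 alone, those in replicate 1 were 0.43, 0.44 and 0.49, and the last run then reached from 33508 to the last number, 33643.

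**Figure D3:**
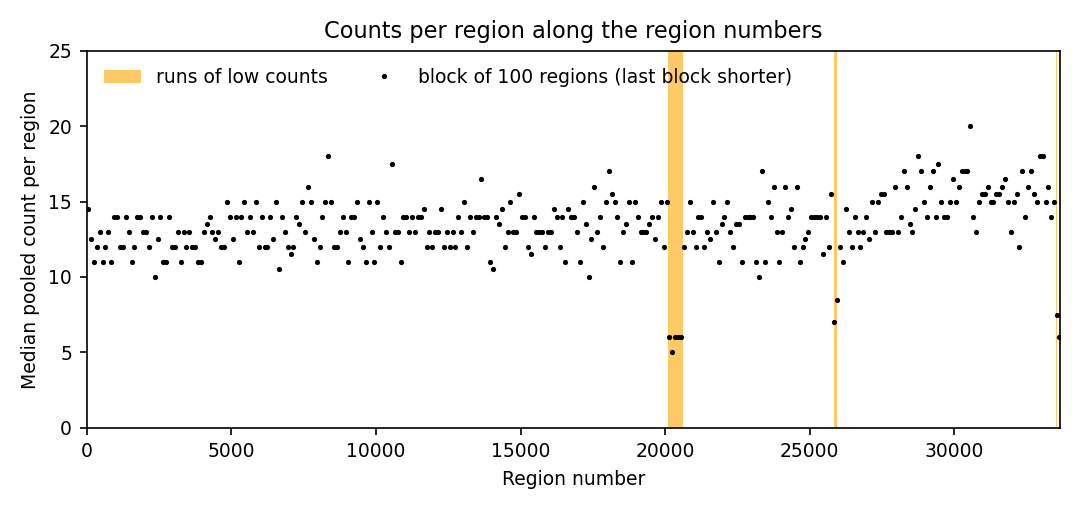
Median pooled count per region (y axis) in blocks of 100 consecutive region numbers (x axis), one point per block; orange bands mark the 3 runs of low counts. Blocks inside the first run sit at 5 to 6, and the median over the full blocks outside the runs is 13.5.

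Regions with high counts were more frequent in the later numbers. Of the 20112 regions before the first run, 778 (3.87%, exact binomial 95% interval 3.61% to 4.14%) had 55 or more pooled counts, the 95th percentile of all regions. Of the 5201 regions between the first and second runs, 379 (7.29%, 6.60% to 8.03%) reached this level. Of the 7564 regions between the second run and the third, 544 (7.19%, 6.62% to 7.80%) did. The medians of these parts lay closer together, at 13, 13 and 15 pooled counts. The intervals treat regions as independent, and they can be too narrow, since regions with high counts adjoined each other more often than in shuffles. Region lengths are not used here, so a difference in the mark itself is not shown.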

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

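The agreement of the libraries depended on the scale. The Pearson r across regions was 0.72 with a pseudocount of 0.5, 0.655 with 0.1 and 0.748 with 1. It was 0.941 on untransformed counts and 0.747 in regions above the median, and quantile normalization left it at 0.72. The chi-square ratio of 1.00 stayed within sampling noise in regions with 10 or more pooled counts and in those above the median, alternatives added after the data were seen. The 1452 regions shared in the top 5% became 290 in the top 1% and 2755 in the top 10%, by construction of the threshold. Quantile normalization and median centring could not move this number, since the threshold is a rank within each library. Each library alone gave 1712 and 1723. The 6885 regions 2-fold or more apart became 14713 at 1.5-fold, 1206 at 4-fold and 1927 above the median of the mean. They were 6611 after quantile normalization and 7416 after median centring. The exact binomial test, added later, called 0 of these regions. The larger share of replicate 1 in the strongest regions was 52.2% at 400 or more counts and 48.9% at 200 or more. Before the first low run it was 52.7%, and in later numbers it was 49.3% and did not pass the test (two-sided exact binomial p = 0.25). The settings foreseen for gene lists, chromosomes and overlaps of regions were not run, because the files give no positions or names. Depth limits single regions: the median region has 13 pooled counts.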

Other observations

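The tests in this part were chosen after the patterns were seen. The predictions for the 10th percentile, for neighbours without the low runs, for the strongest regions without the first 2 and for the largest departure of the strongest regions were written before those values were computed. With no second group in the design, no biological explanation was tested between samples.

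Counts at neighbouring region numbers were weakly correlated. The counts of one replicate correlated with those of the other replicate at the next number at Spearman rho = 0.15 (mean of both directions), against 0.69 at the same number. Among 100 shuffles of the region order the highest value was 0.01, which argues against a chance order. With the 3 low runs left out the value was 0.14, so these runs alone do not account for it. With all regions kept, the correlation fell from 0.15 at the next number to 0.09 at a distance of 2 numbers, 0.04 at 10 and 0.02 at 100. These larger distances were not computed without the runs. Regions with 55 or more pooled counts stood next to each other in 188 pairs, against a median of 86 in shuffles (range 60 to 109). The levels around strong regions differed little from those around others. The 10 neighbours had a median of 15.5 pooled counts around regions with 300 or more, and 13.5 around those with 10 to 19. A candidate explanation is that the numbers follow genomic position and the mark covers neighbouring regions, and this stays open because no positions are used here.

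The runs of low counts at 20113 to 20633, 25835 to 25939 and 33504 to 33558 may mark places where the list of regions starts again, which was not tested. In 100 shuffles of blocks of 20 neighbouring numbers, 0 held a run scoring as high as the second run, and 8 held one scoring as high as the third. The 3 runs were left out of these shuffles, so their own low blocks could not add to the scores. In 100 shuffles of all single regions, the runs included, the highest score was 7.2, against 102.3 and 16.5 for the first 2 runs. The third run (10.5) and the next-ranked run (9.5) also exceeded it, so these shuffles do not set the first 2 runs apart. The block shuffles reached up to 14.2, which argues against a chance order of blocks from outside the runs for the first 2. Chance stays open for the third, whose far edge is uncertain. A loss of strongly marked regions over the same background would leave the 10th percentile equal. That of the first run was lower, 2 pooled counts against 6, a ratio of 0.33 (95% bootstrap interval 0.17 to 0.33). The run was chosen for counts at or below the median, which also lowers this percentile, so such a loss is not excluded. The animal was male, and a hypothesis is that the runs hold X-linked regions, present in 1 copy per cell; a halving as the only difference would give 0.5, and the first run lay below it, at 0.43 (0.40 to 0.46). Its interquartile mean of 5.71 was under the 6.28 to 7.12 that halved preceding counts gave, though its median of 6 was at the edge of their 6 to 7. The second run also lay below a halving by this measure, at 0.38 (0.32 to 0.45), and by its ratio of medians (0.31 to 0.46), while the wider interval of its ratio of means (0.32 to 0.62) held 0.5. With edges from the other library, the first run stayed at 0.43, and the second was at 0.34 in replicate 2 and 0.44 in replicate 1. The intervals for the runs treat regions as independent, and the halved counts were not searched for runs. The intervals can thus be too narrow and the pooled ratios too low. The third run, at 0.40 (0.31 to 0.50) pooled, had intervals of 0.34 to 0.56 in replicate 1 and 0.26 to 0.47 in replicate 2, a ratio of means of 0.32 (0.26 to 0.38), and 0.49 with the edges of replicate 2, so that its ratio depends on where it ends. A lower copy number together with shorter or less mappable regions stays open, as does a difference in the regions alone, since lengths and positions are not used here.

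The strongest regions held a larger share of replicate 1 than other regions. As the level of 300 was set after the values were seen, the largest departure over every number of strongest regions up to 1682 was set against 1000 binomial splits. It was larger than in any of them (p = 0.001, the smallest they can give), which argues against independent sampling noise, and 1 or 2 regions alone are argued against by the value without the first 2 (p = 2.3e-06, exact binomial). These tests treat counts as independent, which duplicate reads would break. All 8 of the strongest regions before the first low run lay above replicate 1's share of all counts, with 52.7% from replicate 1. The 7 later ones were at 49.3% (two-sided Fisher's exact test on counts, p = 0.0059), and 4 of them lay above that share. The earlier regions had 345 to 1142 pooled counts and the later ones 317 to 435. Position and level therefore cannot be told apart in this comparison. Reads that align to several copies of a repeat, or duplicates kept unevenly, may differ between the libraries in this way, and neither could be tested with these counts.

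Regions with at least 50 and fewer than 300 pooled counts took 47.9% of their counts from replicate 1 (95% interval 47.7% to 48.1%), against 48.2% of all counts (two-sided exact binomial p = 0.019, not adjusted).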
